A study of Homo sapiens with 4 samples.

How the data were processed

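Total RNA from 4 samples of SH-SY5Y cells, a human neuroblastoma line, was profiled on 3'-labelled oligonucleotide arrays, 1 array per sample. Per the labels' protocols, small interfering RNA against TSPAN8 was delivered with a self-delivering (Accell) system, cells were incubated for 72 h, and 100 ng of total RNA was amplified and labelled with biotin. The groups were TSPAN8 knockdown (2 arrays) and transfection control (2 arrays). What the control cells received beyond the word control is not given in the sources used here, nor is the sequence of the small interfering RNA. Nothing in the labels says that the 2 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

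The deposited values are on a log2 scale, 1 per probe set and array. RMA (robust multi-array average, which comprises background correction, quantile normalization and a summary over the probes of a set) and R 3.0.1 are named in the submitters' processing notes, without settings. The sorted values of the 4 arrays deviated from their mean by at most 0.082, so the distributions were nearly but not exactly equal. Values ran from 5.30 to 14.6, with array medians between 6.58 and 6.61. The table holds 54675 probe sets, of which 62 are AFFX controls that were left out of the tests. Scanner files, detection calls and scan dates were not used here, so background could not be assessed probe by probe and no batch could be examined. Summarised log2 values compress the change of transcripts near background. The number of arrays limits the precision.

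Genes were named through the platform annotation of the array. Of the 54613 tested probe sets, 41091 had 1 gene, 1801 had several and were not named, and 11721 were not listed. Of the single-gene probe sets, 41037 matched a current reference identifier and none needed a new symbol. Each of 19775 genes was represented by its probe set with the highest mean over the 4 arrays. Disagreement in sign between probe sets is stated for the genes named in the text, except DCN, LUM, VIM, COL1A2, FN1 and TAGLN. For these 6 genes only the representative probe set is given. No genome coordinates are printed because no build is named for these values.

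Knockdown was compared with control by limma 3.58.1 (lmFit and eBayes, default settings, R 4.3.3) on the deposited log2 values of all 4 arrays, without covariates, with Benjamini-Hochberg adjustment over the 54613 probe sets and a threshold of 0.05. All p-values are two-sided. Changes are log2 differences, knockdown minus control, with limma's standard error. There was 1 comparison between groups. The moderated variance had 5.80 prior degrees of freedom and a prior SD of 0.059. Data were simulated 20 times with these variances, with 50 of the 54613 probe sets changed at each size. The test recovered 51.8% of log2 changes of 0.4, 92.9% of 0.6, 99.1% of 0.8 and 99.8% of 1.3, beside a mean of 8.15 false calls. All 200 changed probe sets shared each simulation, which eases the Benjamini-Hochberg cut-off, and the noise was independent between probe sets. These shares therefore do not carry over to the real data, where 1 probe set passed and a measured change of 0.78 did not.

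The test, the samples, the rule for named genes, 24 gene lists and the alternatives were fixed before the data were examined. The rule named TSPAN8, up to 12 genes per direction with the largest change past the threshold and no overlap between the groups' arrays (filled up, where fewer passed, with genes changed by at least 0.58 on the log2 scale, by p), and the 4 members of each list with the smallest p. The lists, which hold 620 measured genes, were tested with camera (preset correlation 0.01, Benjamini-Hochberg adjustment over the 24 lists), which compares a list with all other genes. Camera with an estimated correlation and fry, which tests whether the members move on balance one way without reference to other genes, were alternatives. A list was moved by 0.3 in 20 simulations with noise independent between genes, so genes that vary together were not covered. Camera called the moved list 20 times with the preset and 0 times with an estimated correlation. At 0.5 it called the list 20 and 4 times. Lists that had not been moved were called 2, 1 and 0 times with the preset at shifts of 0.1, 0.3 and 0.5, and 0 times with an estimated correlation. These sizes were added after a shift of 0.1, called 20 times with the preset and 0 times with an estimated correlation, had been seen. Other alternatives were filters on dim probe sets, a second quantile normalization, median centring, a trended robust variance, array weights, the replicate number as a block, removal of probe sets that can bind several transcripts, other summaries per gene, other thresholds, and leaving out each array in turn. Python 3.11.15 and matplotlib 3.10.9 drew the figures.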

Results

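The series asked how the transcriptome of SH-SY5Y cells responds when TSPAN8 is silenced. TSPAN8 encodes tetraspanin 8, a cell-surface protein with 4 membrane-spanning segments that organises membrane complexes with integrins and other adhesion molecules. Expression of 54613 probe sets was measured in 2 knockdown and 2 transfection control samples collected after 72 h. The arrays were nearly alike: Pearson's r across probe sets, which are not independent replicates, was 0.998 within the knockdown group and 0.998 within the control group, and between 0.997 and 0.998 across groups. Knockdown replicate 2 correlated more closely with each control array than with knockdown replicate 1. The median absolute difference between 2 arrays was 0.064 (log2) for the knockdown pair, 0.058 for the control pair and 0.062 to 0.067 between groups. RNA integrity, read from control probe sets, did not separate the groups. The 3' minus 5' difference for ACTB was 2.00 and 2.18 on the knockdown arrays and 2.14 and 1.98 on the control arrays, and for GAPDH it was 0.56 and 0.67 against 0.60 and 0.53.

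TSPAN8 fell after knockdown, from a log2 value of 7.57 ± 0.072 (SD, n = 2) in control cells to 6.30 ± 0.072 (SD, n = 2) in knockdown cells. The change was -1.27 ± 0.062 (SE), with a 95% confidence interval of -1.41 to -1.12, which leaves 41.5% of the control signal, any background included (limma, adjusted p = 0.0026). The values were 6.25 and 6.35 on the knockdown arrays and 7.52 and 7.62 on the control arrays. TSPAN8 ranked at percentiles 69.6 and 70.9 of all probe sets in control cells and at 34.4 and 38.7 in knockdown cells, below the array median. A single probe set represents the gene.

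TSPAN8 was the only probe set of the 54613 to pass the threshold (limma, adjusted p under 0.05), with 0 higher and 1 lower. No other probe set changed by a log2 value of 1 or more in either direction, and 7 in all changed by at least 0.58. At an unadjusted p under 0.05 there were 4278 probe sets, 2030 higher and 2248 lower, against 2731 expected with no effect. The groups' arrays did not overlap for 20489 probe sets (37.5%), where chance gives 33.3%. The number of calls rose with either knockdown array left out and stayed the same with either control array left out. In such fits the lone remaining array is assumed to vary like the other group. A deviation of that array cannot be told from an effect of the knockdown, so those counts, given below, do not measure a larger response.

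**Figure D1:**
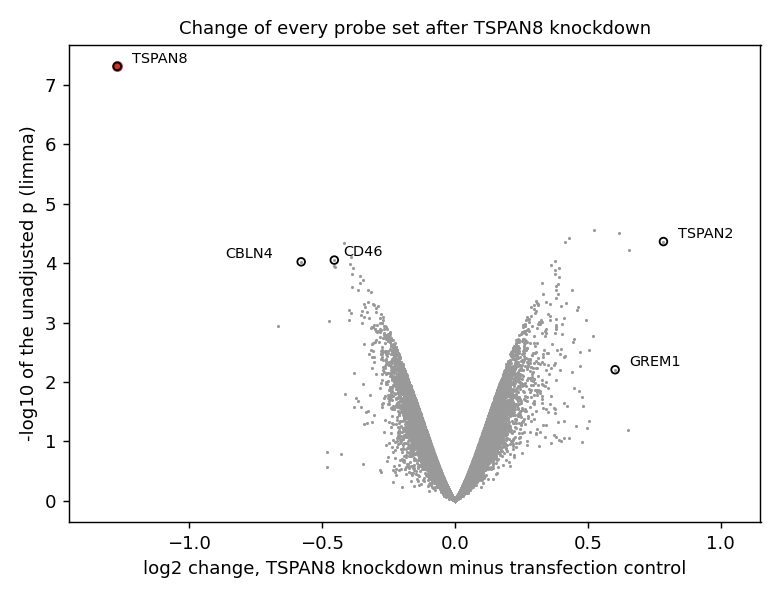
The log2 change of each of the 54613 probe sets (x axis, knockdown minus control, n = 2 arrays per group) against -log10 of limma's unadjusted p (y axis). TSPAN8 at -1.27 is the only point past the adjusted threshold (red), and TSPAN2, GREM1, CBLN4 and CD46 are circled for orientation, CBLN4 having been chosen after its value was seen.

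TSPAN2, another tetraspanin, had the largest measured increase. It stood at 7.36 ± 0.22 (SD, n = 2) in knockdown and 6.58 ± 0.060 (SD, n = 2) in control cells, a log2 difference of 0.78 ± 0.096 (SE) that did not pass over all probe sets (limma, adjusted p = 0.36) but passed when adjusted over the list alone (0.0013). Its other 2 probe sets differed by 0.069 and 0.056. GREM1, a secreted antagonist of bone morphogenetic proteins, was the only other gene named by the rule above 0.58, at 0.60 ± 0.16 (SE; limma, adjusted p = 0.60), with values of 7.74 and 7.13 on the knockdown arrays and 6.84 and 6.83 on the control arrays. Besides TSPAN8, no gene named by the rule was lower by as much.

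The other tetraspanins did not pass as a set. Of 31 measured members, 0 passed over all probe sets and 1, TSPAN2, passed when adjusted over the list alone. TSPAN4 (-0.18), TSPAN11 (-0.15) and TSPAN18 (-0.14) followed by p. The median member differed by -0.0063 (camera, adjusted p = 0.91), with a mean of 0.0014 of the opposite sign. Among 30 integrins and other partner or adhesion molecules, 0 passed over all probe sets and 1 passed when adjusted over the list alone. That gene was CD46, a complement regulator, at -0.45 ± 0.061 (SE; 0.0027 over the list, 0.37 over all probe sets by limma). Only 1 of its 3 probe sets differed at an unadjusted p under 0.05, and 1 was above control, at 0.032. L1CAM, a neural adhesion molecule, differed by -0.20 (0.025 at its other probe set) and the integrin subunit ITGA6 by 0.15 (0.079 to 0.22 with 1 array left out), neither past the threshold. The median of this list was 0.020 and its mean -0.0063 (camera, adjusted p = 0.65).

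**Figure D2:**
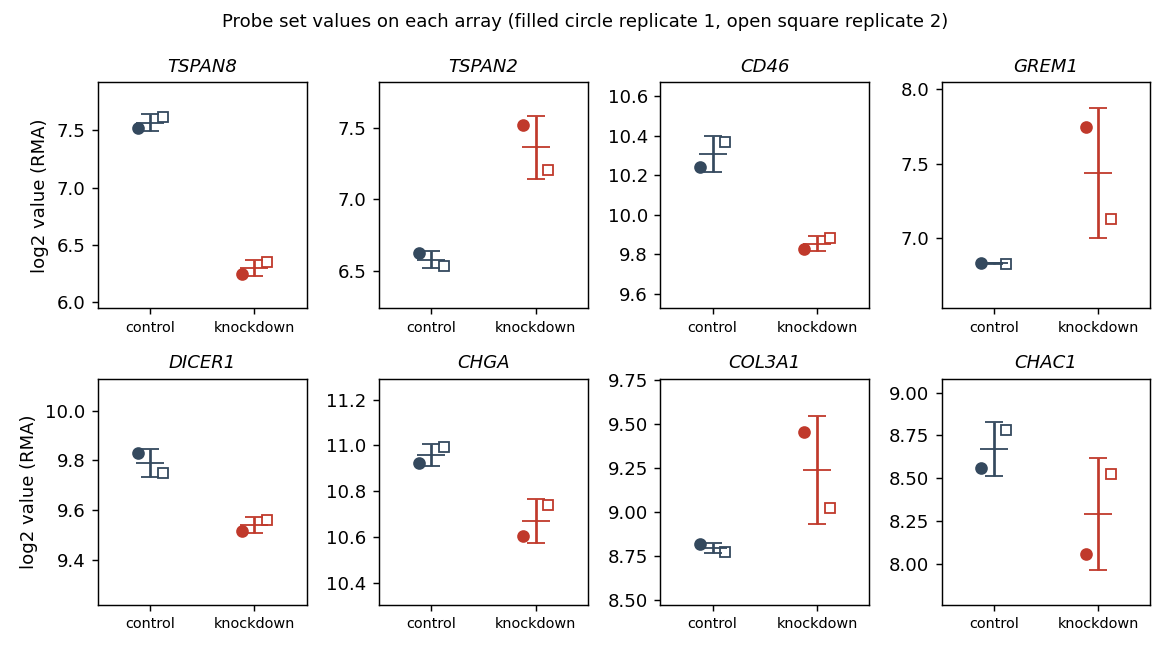
Log2 values of 8 genes on each array (y axis, separate range per panel), with filled circles for replicate 1, open squares for replicate 2, horizontal marks for group means and bars for SD (n = 2); the genes were picked from the named genes after their values were seen. The groups lie apart by 1.27 for TSPAN8, and knockdown replicate 1 stands apart from knockdown replicate 2 for GREM1 and COL3A1.

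Of the preset lists, 4 of 24 passed the list test with a preset correlation (camera), each with 0 members past the threshold over all probe sets. None of them passed by camera with an estimated correlation (adjusted p = 0.90 for each). The estimates were 0.94 for the stress response list, 0.21 for the mesenchymal list, 0.0058 for the neuronal list and -0.061 for the RNA interference list. For the neuronal and RNA interference lists the estimate lay below the preset of 0.01, so a higher correlation does not account for the lost call. Their unadjusted p was 0.11 and 0.078 (camera, estimated correlation). With simulated noise independent between genes, this setting called a list moved by 0.5 in 4 of 20 runs, and one moved by 0.3 in 0 of 20. Those counts do not carry over to lists whose genes vary together, such as the stress response list. Without control replicate 2, 7 lists passed, and without knockdown replicate 2, 2 passed. RNA interference machinery genes were lower as a set. Of 12 measured members, 10 had a value below control, with a median of -0.090 (camera, adjusted p = 0.012), and fry also called the list (adjusted p = 0.023). Neither test matched genes on signal, and random lists of like mean signal had a median of -0.039. DICER1, the enzyme that cuts small RNA precursors, was at -0.25 ± 0.055 (SE) and was the only member to pass when adjusted over the list alone (0.025). That adjustment leaves out the search over 24 lists, in which 6 of 620 measured members passed in this way. Of the 6 probe sets of DICER1, 5 were below control and 1 was so at an unadjusted p under 0.05. TNRC6B (-0.21, from -0.30 to -0.12 with 1 array left out) and TNRC6C (-0.15), which act with Argonaute proteins in silencing, and the nuclear exporter XPO5 (-0.13) followed, with 3 of the 7 probe sets of TNRC6C and 2 of the 7 of TNRC6B above control. The list median was -0.10 on knockdown replicate 1 and -0.098 on knockdown replicate 2, against 0.00079 and -0.00079 on the control arrays. The call was lost without knockdown replicate 2 (adjusted p = 0.068), after a second quantile normalization (0.085) and among probe sets above the median signal (0.054).

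Neuronal differentiation genes were also lower as a set, with 17 of 25 members below control and a median of -0.056 (camera, adjusted p = 0.044; with an estimated correlation, adjusted p = 0.90). The microtubule motor gene KIF5C (-0.21), the migrating-neuron marker DCX (-0.19) and CRMP1 (-0.19), a gene of axon guidance signalling, were below control, and the neurofilament gene NEFL was at 0.20 (0.10 without knockdown replicate 1); 0 members passed when adjusted over the list alone. The arrays' medians were -0.065 and -0.082 in knockdown cells. This call ended under most alternatives, among them the second quantile normalization (adjusted p = 0.085) and the removal of knockdown replicate 2 (0.35) or of control replicate 1 (0.17).

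Mesenchymal neuroblastoma and fibroblast genes, which mark an alternative cell state or other cells that such a culture could hold, were higher as a set. Of 28 members, 22 were above control, with a median of 0.097 (camera, adjusted p = 1.7e-06; with an estimated correlation, adjusted p = 0.90), and 0 passed when adjusted over the list alone. COL3A1 (0.44 ± 0.12, SE), SNAI2 (0.34 ± 0.15, SE), CCN1 (0.29 ± 0.070, SE) and SPARC (0.26 ± 0.084, SE), genes of matrix, of mesenchymal transition and of matrix signalling, had the smallest p. The value of COL3A1 was the largest of its 5 probe sets, whose median was 0.19 and lowest 0.0021. Without knockdown replicate 1, COL3A1 was at 0.23, SNAI2 at 0.065 and SPARC at 0.13. Knockdown replicate 1 carried most of this difference, at a list median of 0.15, against 0.042 on knockdown replicate 2 and 0.013 and -0.013 on the control arrays. Without knockdown replicate 1 the median was 0.042 (adjusted p = 0.018).

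Genes of the unfolded protein and integrated stress response were lower as a set, with 29 of 30 below control and a median of -0.18 (camera, adjusted p = 5.5e-06; with an estimated correlation, adjusted p = 0.90). CHAC1 (-0.38), the stress-induced SESN2 (-0.33), DDIT4 (-0.24) and the amino acid transporter subunit SLC3A2 (-0.18) had the smallest p, and 0 members passed when adjusted over the list alone. With 1 array left out CHAC1 ranged from -0.61 to -0.15, SESN2 from -0.53 to -0.14, DDIT4 from -0.32 to -0.15 and SLC3A2 from -0.26 to -0.097. The arrays within each group differed by more than the groups, and replicate 1 was the lower one in both groups, by a list median of -0.32 between the knockdown arrays and -0.30 between the control arrays. The list median was -0.33 on knockdown replicate 1 and -0.034 on knockdown replicate 2, the latter lying between control replicate 1 (-0.15) and control replicate 2 (0.15). Without knockdown replicate 1 the call ended with a median of -0.034, and likewise without control replicate 2 with a median of -0.025. Leaving out 1 array unbalances the replicate numbers, so these fits mix the shift with the number and the difference between groups. Within numbers 1 and 2, knockdown minus control was -0.20 and -0.15, each from 1 pair of arrays that no label pairs.

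**Figure D3:**
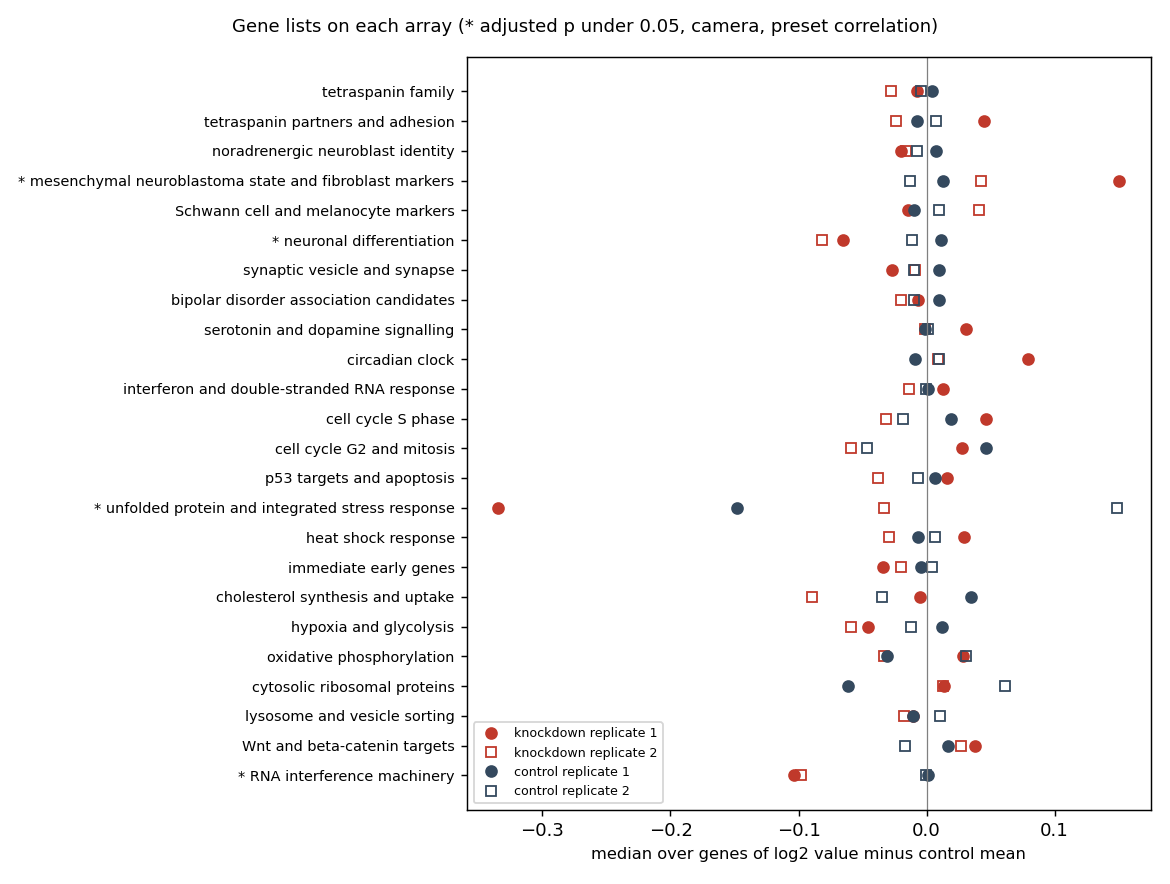
The median over the genes of each list of the log2 value minus the mean of the 2 control arrays (x axis), for each array (red knockdown, blue control; filled circles replicate 1, open squares replicate 2). Both knockdown arrays lie near -0.10 for RNA interference machinery. For the stress response list knockdown replicate 2 lies between the control arrays, and replicate 1 is the lower array in both groups.

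Noradrenergic identity genes did not pass as a set (26 measured, median -0.021, camera, adjusted p = 0.66), but 6 were lower and 0 higher at an unadjusted p under 0.05. CHGA, a secretory granule protein, was at -0.29 ± 0.063 (SE), the noradrenaline-synthesising enzyme DBH at -0.35 ± 0.10 (SE), HAND1 at -0.23 and EYA1 at -0.21, with CHGA and EYA1 at 0.050 adjusted over the list alone, just above the threshold. DBH was at -0.53 without knockdown replicate 2 and at -0.17 without knockdown replicate 1. The second probe sets of DBH and EYA1 were above control, at 0.037 and 0.16. Schwann cell and melanocyte markers, the other set for cells of another type, did not pass either (13 measured, median 0.021, adjusted p = 0.21), and its SOX2 was at 0.22 with overlapping arrays (0.033 to 0.41 with 1 array left out). Synaptic genes had a median of -0.028 (31 measured, adjusted p = 0.42), with STX1A at -0.18. Among 28 candidate genes from association studies of bipolar disorder the median was -0.0094 (adjusted p = 0.70), with ZNF804A at -0.26 (-0.17 without knockdown replicate 1), MAD1L1 at -0.25, DGKH at -0.18 and SYNE1 at 0.14; the probe sets of DGKH and SYNE1 disagreed in sign. Serotonin and dopamine signalling genes had a median of 0.029 (22 measured, adjusted p = 0.21), with the receptor gene HTR2B at 0.19, and without knockdown replicate 1 the median was -0.0011. Circadian clock genes had a median of 0.032 (19 measured, adjusted p = 0.12), with BHLHE40 at 0.29 (0.055 at its other probe set). The median of this list was 0.079 on knockdown replicate 1 and 0.0088 on knockdown replicate 2. Each of these lists had 0 members past the threshold over all probe sets.

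The interferon and double-stranded RNA response, which introduced RNA can provoke, did not pass as a set (37 measured, median -0.0049, camera, adjusted p = 0.66). USP18, a negative regulator of interferon signalling, was at -0.39 ± 0.057 (SE; limma, adjusted p = 0.39 over all probe sets, 0.0056 adjusted over the list alone), while SAMD9L was at 0.17. Cholesterol genes had a median of -0.046 (19 measured, adjusted p = 0.091), at -0.0054 on knockdown replicate 1 and -0.090 on knockdown replicate 2, and STARD4, a sterol carrier, passed only when adjusted over the list alone (-0.30, 0.024). Of the Wnt targets (19 measured, median -0.0066, mean 0.027, adjusted p = 0.30), TNFRSF19 passed only over the list alone (-0.30, 0.027), with 1 of its 3 probe sets at an unadjusted p under 0.05 and 1 above control at 0.049, and SOX9 was at 0.41. SOX9 had values of 8.71 and 8.06 on knockdown replicates 1 and 2 and of 8.02 and 7.93 on the control arrays.

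Housekeeping and growth lists did not pass with camera. The adjusted p was 0.30 for S phase genes (median 0.0097), 0.72 for G2 and mitosis (-0.023), 0.93 for p53 targets and apoptosis (0.0045, mean -0.0093), 0.70 for the heat shock response (-0.0081), 0.65 for immediate early genes (-0.023), 0.21 for hypoxia and glycolysis (-0.054), 0.99 for oxidative phosphorylation (-0.0015), 0.13 for cytosolic ribosomal proteins (0.014) and 0.86 for lysosome and vesicle sorting (-0.025). The members with the smallest p in these lists included MCM7 (-0.16), AURKB (-0.17), PLK2 (0.33), DNAJA1 (0.14), DUSP6 (-0.16), BNIP3L (-0.16), NDUFV1 (-0.21, but 0.055 at its other probe set), RPLP2 (0.11) and HGS (-0.16), and none passed over all probe sets or over its list alone. With 1 array left out, PLK2 ranged from 0.12 to 0.55, RPLP2 from 0.029 to 0.19, DUSP6 from -0.24 to -0.085, DNAJA1 from 0.078 to 0.21, MCM7 from -0.22 to -0.10 and HGS from -0.22 to -0.10. The median, the mean and the direction of the test did not share a sign for the interferon, heat shock, p53, Wnt, tetraspanin family and tetraspanin partner lists.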

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

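The alternatives were chosen before the data were examined, whereas the medians within a replicate number and the count of moved probe sets below were added afterwards. TSPAN8 kept its direction under every alternative run and its call under all but 1: with the replicate number as a block its change was -1.27 with an adjusted p of 0.16, and 0 probe sets passed, in a fit that leaves fewer residual degrees of freedom. Deviations of equal replicate numbers correlated at 0.051 across all probe sets, from 2 pairs, and nothing in the labels pairs them, but some lists moved with the number in both groups: replicate 1 minus replicate 2 was -0.32 and -0.30 (knockdown, control) for the stress response and 0.087 and 0.093 for G2 and mitosis. Knockdown minus control within numbers 1 and 2 was -0.20 and -0.15 for the stress response list, and whether the numbers mark a shared day is open. Leaving out each array in turn gave TSPAN8 changes from -1.32 to -1.22. The count of probe sets ran from 1 to 1026: 1026 without knockdown replicate 2, 25 without knockdown replicate 1, and 1 without either control array, where the lone remaining array is assumed to vary like the other group. At an unadjusted p under 0.01 with a log2 change of at least 0.58 there were 6. The cause of these shifts was not tested. The number of lists called was 4, against 2 after a second quantile normalization, 0 by camera with an estimated correlation and 1 by fry, and from 2 to 7 with an array left out.

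Outside leave-one-out, the direction of the test turned in 22 cases, all for lists without a call, whose medians were close to 0. Among probe sets above the median signal these were the tetraspanin family (-0.0089), interferon (-0.027), G2 and mitosis (-0.023), oxidative phosphorylation (-0.0015, and also -0.0015 among values above 6) and lysosome (-0.025). After a second quantile normalization they were interferon (-0.014), G2 and mitosis (-0.0018), oxidative phosphorylation (0.0093) and lysosome (0.00011). Without probe sets that can bind several transcripts they were the tetraspanin family (-0.0082), heat shock (-0.0050) and oxidative phosphorylation (-0.0015). With fry they were tetraspanin partners (0.020), interferon (-0.0049) and p53 targets (0.0045). With the mean over a gene's probe sets they were bipolar candidates (0.0091) and oxidative phosphorylation (0.0017), and with the smallest p per gene the tetraspanin family (-0.0092), bipolar candidates (0.0068), G2 and mitosis (-0.0043) and oxidative phosphorylation (0.011). The cause was not tested.

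With an array left out, the test turned for these results, given as the range of medians or changes: tetraspanin family -0.028 to -0.0074, tetraspanin partners -0.024 to 0.045, bipolar candidates -0.020 to 0.0011, S phase -0.031 to 0.047, G2 and mitosis -0.073 to 0.033, p53 targets -0.038 to 0.016, stress response -0.33 to -0.025, heat shock -0.030 to 0.029, oxidative phosphorylation -0.034 to 0.041, ribosomal proteins -0.051 to 0.078, lysosome -0.034 to -0.010, RPL3 -0.11 to 0.012 and the least changed MALAT1 probe set -0.067 to 0.24. For lists whose test kept its direction but whose median moved by over 1.5 times, the ranges were -0.090 to -0.0054 (cholesterol), 0.0088 to 0.079 (circadian clock), -0.0011 to 0.031 (serotonin and dopamine), -0.014 to 0.041 (Schwann cell), -0.040 to -0.014 (noradrenergic), -0.039 to -0.0092 (synaptic), -0.059 to -0.026 (hypoxia), -0.039 to -0.017 (immediate early), -0.023 to 0.013 (interferon), -0.010 to 0.038 (Wnt), -0.088 to -0.064 (neuronal) and 0.042 to 0.15 (mesenchymal). For the stress response list the test turned without knockdown replicate 1. No named probe set changed direction or call in the settings that kept all 4 arrays, apart from TSPAN8 as given above. Centring moved no array's median by more than 0.020. Of 129 named probe sets other than that of TSPAN8, 61 moved by over 1.5 times with an array left out. Background was not measured per probe set here, so how far it limits the size of the change in TSPAN8, or of other dim probe sets, was not assessed.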

Other observations

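The genes in this paragraph were chosen after their values were seen, and none passed the adjusted threshold (limma, Benjamini-Hochberg). MALAT1, a long non-coding RNA retained in the nucleus, was above control at 12 of 12 probe sets, with a median of 0.39 (range 0.085 to 0.66), and 10 had an unadjusted p under 0.05. PHLDA1 was below control at 6 of 6 probe sets (median -0.37). The transcription factor gene DACH1 (-0.40) and the lipid phosphatase gene PLPP3 (-0.24) were below control at 3 of 3 probe sets each. The secreted synaptic protein gene CBLN4 was at -0.58 and -0.20 and ST3GAL5, a ganglioside synthesis gene, at -0.39. INSM1, a neuroendocrine transcription factor, was at -0.45 and -0.03. DKK2 and BDP1 stood out at 1 probe set each (0.52 and 0.42) but their others disagreed, at -0.14 for DKK2 and at 0.08 and -0.10 for BDP1. With 1 array left out, these 2 probe sets of BDP1 ranged from 0.052 to 0.12 and from -0.15 to -0.054, the second of INSM1 from -0.042 to -0.018, 1 of DACH1 from -0.36 to -0.16, 1 of PHLDA1 from -0.097 to -0.022, and 2 of MALAT1 from -0.067 to 0.24 and from 0.10 to 0.38.

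Agreement between probe sets did not set the groups apart from a split by replicate number. Of 5508 genes with at least 3 probe sets, 12 had all of them at an unadjusted p under 0.05 in 1 direction (4 higher, 8 lower), against 16 when replicates numbered 1 were set against those numbered 2, and 0 in the crossed split. Single probe sets at that p numbered 4278 in the real split and 2040 and 1753 in the others, and 3 splits are too few for a share under 0.05. The split by replicate number is not free of effects either, since some lists moved with that number in both groups. In both other splits a difference between knockdown and control adds to the residual spread, which lowers their counts. These counts therefore do not decide whether the knockdown changed genes with several probe sets. Changes from disjoint pairs of arrays correlated at 0.17 and 0.12 across probe sets, which are not independent replicates.

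Of the tests below, those on the mesenchymal list and on the MALAT1 probe set type were chosen after the result was seen, and for the RNA interference list the condition on the bootstrap intervals was added after its value was seen. Mesenchymal and fibroblast genes were higher by a median of 0.14 on knockdown replicate 1 than on knockdown replicate 2 (bootstrap over genes 0.040 to 0.26). A larger share of fibroblast-like cells in that sample may account for this: the list medians meet what it was taken to need, but those bounds were set once the medians were known, so this is no independent test. Its abundant genes differed unevenly between the 2 knockdown arrays. These differences were 0.86 for DCN, 0.46 for LUM, 0.43 for COL3A1, 0.25 for VIM, 0.13 each for COL1A2 and FN1 and 0.030 for TAGLN. A further requirement on COL1A2, FN1 and TAGLN was tried after their values were seen. These genes failed it, which left the outcome undecided, and the requirement was then dropped. The explanation therefore stays undecided. On knockdown replicate 2, COL3A1, COL1A2, DCN and LUM were above the control mean (0.23, 0.082, 0.064 and 0.043). FN1, VIM and TAGLN were below it (-0.097, -0.065 and -0.041). Knockdown replicate 2 stood at 0.042 above the control mean (0.014 to 0.065), less than the other knockdown array, so an effect of the knockdown on the list is open too.

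A larger share of nuclear or unspliced RNA in the knockdown samples could raise MALAT1. It was taken to raise probe sets that are named to no gene as well, although what these measure was not examined. The median change of 3020 such probe sets was compared with that of named ones within bins of like signal. Averaged over the bins, weighted by how many such probe sets each held, the difference between medians was 0.016 (bootstrap 0.012 to 0.021). This lies above 0 but below the 0.05 that the explanation was set to need, so a smaller share is not excluded. Cross-hybridisation stays open: 7 of the MALAT1 probe sets are of the x_at type and all but 1 of the other 5 of the s_at type, both of which can bind several transcripts, and the 1 without either ending was at 0.085 (95% interval -0.13 to 0.30), with overlapping arrays and at -0.067 without control replicate 2. That the knockdown itself raises MALAT1 is a hypothesis, untested beyond these arrays, and an effect of the particular small interfering RNA on other targets is open.

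RNA interference machinery genes were lower on both knockdown arrays. For the list medians as measured, a single deviating array is argued against: of the 4 differences between a knockdown and a control array, the one nearest 0 was -0.074. These differences were not corrected for signal, so the excess over genes of like signal was not tested for each array. The bootstrap intervals over genes, within each knockdown array, were -0.17 to -0.033 and -0.13 to -0.034. They end only just outside the 0.03 from 0 that this explanation allowed. These intervals measure the spread over genes and not that between arrays or cultures. A trend with signal shared by other genes may contribute, since 3.22% of 10000 random lists matched on mean signal had a median as low, between the 1% and 5% bounds set beforehand, and the random lists themselves had a median of -0.039. Whether loading the pathway with introduced RNA or the loss of TSPAN8 lowers these genes cannot be separated here, as what the control cells received is not known.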
